A study of Mus musculus with 16 samples.

How the data were processed

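The deposited files give 1 line per read pair with 11 columns. Each end is placed at the midpoint of its restriction fragment, cut at GATC, and a mapping quality, the score of the deposited files per the labels, is given for both ends. Scores were at least 30 in trunk and 31 in limb and at most 42, and were not used further. Both ends of every pair lay within the captured region, no pair lay within 1 fragment, and between 2.75 and 9.80% of pairs repeated the fragment pair of another. The median separation was 247500 to 285914 bp in trunk and 248069 to 272589 bp in limb, and 10073 to 10213 fragments were seen per library. Read trimming and alignment used cutadapt 1.16, Bowtie2 2.2.6 and SAMtools 1.2, per the submitters' processing notes, with mm10 as the build. The tool that assigned pairs to fragments is not given in the sources used here.

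Genes came from the GRCm38.p6 annotation, whose build is that of the files. The spacing of the 10358 fragment positions was checked against GATC sites of the earlier assembly, and strands of 39 of 40 genes were taken from an earlier annotation by gene name only. No coordinate was converted between builds. Records of Hoxd10 and Hoxd3 start inside or near other genes, which led to the added windows at gene ends.

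Pairs were tallied per pair of 40-kb bins, per pair of 8 regions with C-DOM x T-DOM added (37 pairs), per cluster part and 10-kb bin, per 5-kb window centred on the start site of 12 genes, per pair of such windows (43 that do not overlap) and in a 200-kb diamond at 10-kb positions. Pairs within 10 kb of a viewpoint were left out of its ratio. Each count was divided by a factor from the total of its library in the same distance stratum (10 per decade, 37 strata), relative to the mean of the libraries. Bin pairs and profile bins with at least 10 pairs per trunk library on average were fitted with limma after voom, with robust moderation. The other families were fitted with limma on log2 of the normalized pairs plus 0.5. All 8 trunk libraries entered each fit with genotype as the factor, leaving 4 residual degrees of freedom before moderation. P-values were adjusted by Benjamini-Hochberg within each family and contrast at 0.05. Limb values have exact binomial intervals and no test.

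The fits were tested on simulated data. Bin-pair counts were drawn once, as independent negative binomial values with 1 dispersion of 0.005 in all genotypes. Real replicates spread unequally, with chi-square over degrees of freedom of 1.03 in WT, 1.00 in Del(CBS1), 1.25 in Del(CBS1-3) and 1.36 in Del(CBS1-5). That unequal spread was not simulated. For Del(CBS1-5) against WT, 200 of 6518 bin pairs were changed: 15 of 50 at log2 0.5, 10 of 50 at -0.5, 42 of 50 at 1 and 34 of 50 at -1 were called in the right direction, with 9 false calls among 6318. In simulated data without change, Del(CBS1) against WT gave 1 and Del(CBS1-3) against WT 0 calls. The other families were simulated 200 times without change, as independent Gaussian values with 1 common SD. With the sizes of the region pairs (37), viewpoints (12), gene pairs (43) and insulation positions (420), 5.18, 5.04, 5.07 and 5.00% had p below 0.05. The overlap and unequal spread of the real features were not simulated, so these shares check the fitting step and not those families.

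Genes named were, by a rule set before the data were examined, the 12 viewpoint genes with Atp5g3 and Hnrnpa3, the genes in the 5 bin pairs and 5 profile bins with the largest rise and fall per contrast with WT among those that passed and whose groups did not overlap, and the 3 limb viewpoints with the largest rise and fall. Settings varied, as chosen before the data were examined, were bins of 20 and 80 kb, profile bins of 20 kb, viewpoint windows of 10 kb, insulation windows of 100 and 400 kb, library totals in place of strata, coverage divided out, identical fragment pairs kept once, a pseudocount of 5, no low-count filter, a separation of at least 100 kb, a trend fit in place of voom, a replicate block, fits of only the 2 genotypes, domain limits from insulation minima, all 16 libraries with tissue as covariate, and each trunk library left out in turn. Coverage was the share of a library's pair ends in a bin or region, counted on the same pairs as the contacts. Windows at gene ends and Del(CBS1-5) against Del(CBS1) were added after the data were examined. The footprint search used gaps of at least 20 bp where at least 20 read ends were expected, and 50 bp or 10 ends as alternatives. Read ends lie at fragment midpoints, so a gap held at least 1 whole fragment without ends. In every setting 8, 6 and 8 gaps were examined for Del(CBS1), Del(CBS1-3) and Del(CBS1-5). Sequence variants and gene expression were not analysed here.

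Work was done with R 4.3.3, limma 3.58.1, statmod 1.5.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.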

Results

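Contacts of the mouse Hoxd cluster, whose genes pattern the trunk and the limbs, were measured by capture Hi-C in wild-type (WT) embryos and in homozygous embryos lacking CTCF binding sites (CBS), named Del(CBS1), Del(CBS1-3) and Del(CBS1-5). The captured region spanned positions 72402457 to 76999666 of chromosome 2 (mm10). Trunks at E9.5 gave 2 libraries per genotype, and distal (DFL) and proximal (PFL) forelimbs at E12.5 gave 1 library per genotype and tissue, 16 libraries in all. The question was how contacts between the cluster and the domains on its sides changed when CTCF sites were removed. The trunk libraries held 969206 and 923170 read pairs for WT, 1584987 and 1162409 for Del(CBS1), 1374663 and 848180 for Del(CBS1-3), and 1148454 and 1515113 for Del(CBS1-5). The DFL libraries held 2517425 (WT), 1618945 (Del(CBS1)), 3437896 (Del(CBS1-3)) and 2747764 (Del(CBS1-5)) pairs. The PFL libraries held 2134387, 1916585, 2556200 and 2640499 pairs in the same order.

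The centromeric domain (C-DOM, 73912465 to 74642989) ran from the end of Atp5g3, which encodes a subunit of ATP synthase, to 10 kb before Evx2. The telomeric domain (T-DOM) ran from 10 kb after Hoxd1 to the start of Hnrnpa3, which encodes an RNA-binding protein, split at its midpoint into a proximal T-DOM (74775142 to 75217123) and a distal T-DOM (75217124 to 75659104). The cluster was split into a 5-prime part with Evx2, Hoxd13 and Hoxd12 (74652989 to 74677705), a middle part with Hoxd11, Hoxd10, Hoxd9 and Hoxd8 (74679558 to 74707933) and a 3-prime part with Hoxd4, Hoxd1 and most of Hoxd3 (74721978 to 74765142). The rest of the captured region formed a centromeric and a telomeric flank. Regions, tests, thresholds and the rule for naming genes were chosen before the data were examined. The windows at gene ends, the contrast of Del(CBS1-5) with Del(CBS1) and the fragment described last were chosen after.

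Trunk WT and Del(CBS1-3) shared run 1, trunk Del(CBS1) and Del(CBS1-5) run 2, the limb mutants run 3, and the limb WT libraries, re-analysed from an earlier study, run 4. Only Del(CBS1-3) against WT and Del(CBS1-5) against Del(CBS1) were therefore compared within a run in trunk. Over 6518 pairs of 40-kb bins, replicate counts varied no more than counting error in WT (chi-square over degrees of freedom 1.03) and Del(CBS1) (1.00), and more in Del(CBS1-3) (1.25) and Del(CBS1-5) (1.36). The WT and Del(CBS1) replicates did differ in the distribution of pair distances (1.99 and 2.17), so they were kept as 2 libraries each. The p-values below rest only on the spread between these libraries, pooled over the features of a family by moderation. Against 4 residual degrees of freedom, the prior had 438 for bin pairs, 55.3 for profile bins and 19.7 for viewpoints. It had 1.82 for region pairs, 4.57 for gene pairs and 4.30 for insulation. Very small p-values of bin pairs therefore rest mostly on a spread shared by all bin pairs. The labels describe individually collected trunks but do not exclude technical replicates, and with 2 libraries against 2 the smallest exact permutation p is 0.333. Limb intervals are 95% intervals that cover counting error only.

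Contacts that cross the Hoxd cluster, between the C-DOM and the T-DOM, rose in trunks of all 3 mutants. WT trunks had 87709 ± 281 normalized contacts (mean ± SD, n = 2), Del(CBS1) 93575 ± 167, Del(CBS1-3) 99792 ± 348 and Del(CBS1-5) 103021 ± 394. The log2 changes against WT in limma were 0.093 (SE 0.011, adjusted p = 0.00293), 0.19 (SE 0.011, adjusted p = 6.11e-05) and 0.23 (SE 0.011, adjusted p = 1.25e-05), and both libraries of each mutant lay above both WT libraries. Between the C-DOM and the proximal T-DOM, which holds Mtx2, a gene for a mitochondrial outer membrane protein, WT had 49747 ± 48.4 contacts, Del(CBS1) 54927 ± 186, Del(CBS1-3) 59489 ± 358 and Del(CBS1-5) 62571 ± 739. These were rises of 0.14 (SE 0.013, adjusted p = 0.00157), 0.26 (adjusted p = 5.49e-05) and 0.33 (adjusted p = 1.25e-05). Contacts of the C-DOM with the distal T-DOM rose by 0.082 in Del(CBS1-3) (adjusted p = 0.00195) and 0.086 in Del(CBS1-5) (adjusted p = 0.00118). Their change of 0.023 in Del(CBS1) did not pass (adjusted p = 0.202), and the proximal and distal T-DOM were not tested against each other. The C-DOM to T-DOM rise in Del(CBS1) was lost with coverage divided out (0.048, adjusted p = 0.133), with library totals in place of distance strata (0.18, adjusted p = 0.0918) and with all 16 libraries fitted together (0.019, adjusted p = 0.762). The Del(CBS1) rise with the proximal T-DOM was lost in the same settings (0.084, 0.21 and 0.055; adjusted p 0.0612, 0.0592 and 0.436). With library totals the rises with the distal T-DOM were lost too (0.13 and 0.10, adjusted p 0.10 and 0.177). The Del(CBS1-3) and Del(CBS1-5) rises across the cluster and with the proximal T-DOM passed in every setting tried.

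**Figure D1:**
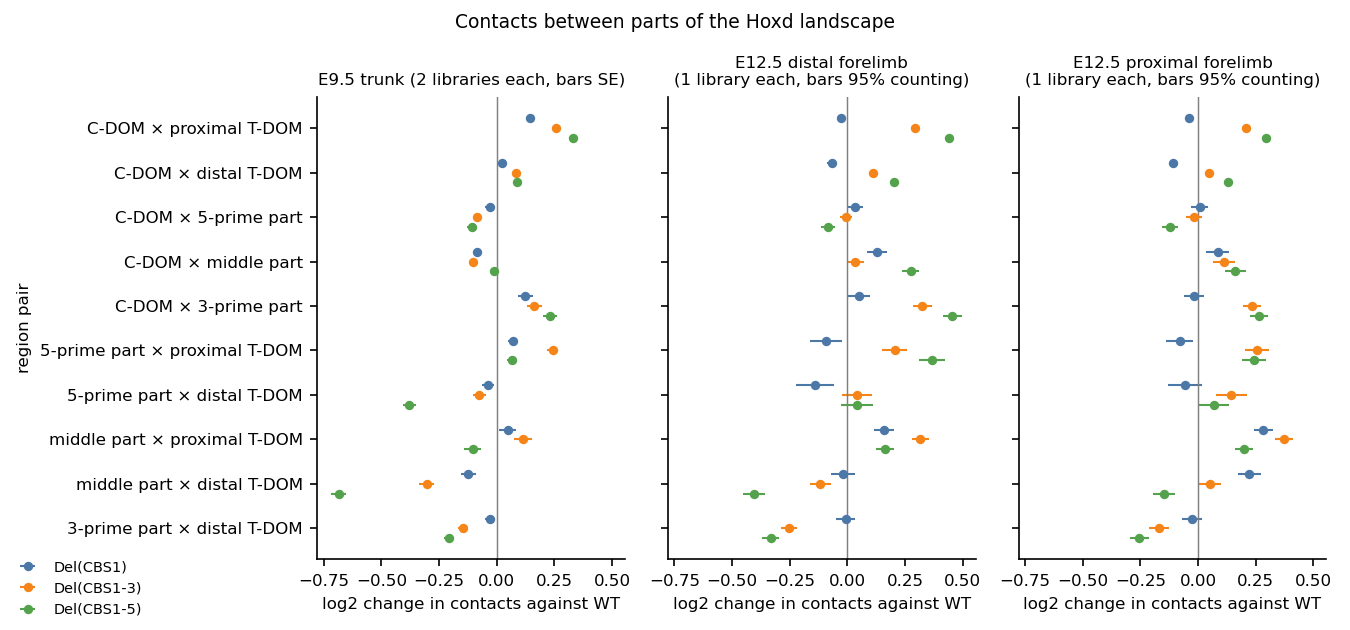
Log2 change in contacts against WT for 10 region pairs in E9.5 trunk (2 libraries per genotype, bars SE) and in E12.5 distal and proximal forelimb (1 library per genotype, bars 95% counting intervals). Colours mark Del(CBS1), Del(CBS1-3) and Del(CBS1-5).

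Contacts of the middle part, which holds Hoxd11 to Hoxd8, with the distal T-DOM fell in trunk with each allele. WT had 4793 ± 140 normalized contacts (n = 2), Del(CBS1) 4399 ± 105, Del(CBS1-3) 3885 ± 135 and Del(CBS1-5) 2981 ± 12. The log2 changes in limma were -0.12 (SE 0.032, adjusted p = 0.0496), -0.30 (adjusted p = 0.000754) and -0.68 (adjusted p = 1.25e-05), with every mutant library below both WT libraries. The fall in Del(CBS1-5) passed in every setting tried on region pairs and was -0.56 with coverage divided out (adjusted p = 1.00e-05). The fall in Del(CBS1-3) was lost only when all 16 libraries were fitted together (-0.17, adjusted p = 0.0532). The fall in Del(CBS1) was lost without WT library 1 (-0.15, adjusted p = 0.0596), WT library 2 (-0.094, 0.209), Del(CBS1) library 1 (-0.099, 0.153), Del(CBS1) library 2 (-0.15, 0.0811) and either Del(CBS1-5) library (-0.12, 0.0785 each). It was also lost with coverage divided out (-0.093, adjusted p = 0.127), with library totals (-0.053, 0.464), with the 2 genotypes fitted alone (0.0914) and with all 16 libraries (-0.011, 0.901).

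The 5-prime part with Evx2, Hoxd13 and Hoxd12 gained contacts with the proximal T-DOM in Del(CBS1-3) and lost contacts with the distal T-DOM in Del(CBS1-5). With the proximal T-DOM, WT had 5540 ± 91.3 contacts (n = 2), Del(CBS1) 5816 ± 97.9, Del(CBS1-3) 6552 ± 166 and Del(CBS1-5) 5800 ± 19.9. The Del(CBS1-3) rise was 0.24 (SE 0.023, adjusted p = 0.000504 in limma), held in every setting tried on region pairs and was seen in both libraries. With the distal T-DOM, WT had 3107 ± 88.0 contacts, Del(CBS1) 3026 ± 3.81, Del(CBS1-3) 2947 ± 50.5 and Del(CBS1-5) 2388 ± 65.2. The Del(CBS1-5) fall was -0.38 (SE 0.028, adjusted p = 0.000109), in both libraries, and was lost only with all 16 libraries (-0.16, adjusted p = 0.102). The 3-prime part with Hoxd4, Hoxd3 and Hoxd1 gained contacts with the C-DOM, by 0.16 in Del(CBS1-3) (SE 0.032, adjusted p = 0.00564) and 0.23 in Del(CBS1-5) (adjusted p = 0.00118). It lost contacts with the distal T-DOM, by -0.15 in Del(CBS1-3) (adjusted p = 0.00261) and -0.21 in Del(CBS1-5) (adjusted p = 0.000486). The loss in Del(CBS1-3) was not called with library totals (-0.13, adjusted p = 0.0557). Within the cluster, contacts of the middle part with the 3-prime part rose by 0.26 in Del(CBS1-3) (adjusted p = 0.00115) and 0.28 in Del(CBS1-5) (adjusted p = 0.000549), in every setting tried on region pairs. Contacts of the middle part with the telomeric flank, beyond Hnrnpa3, fell by -0.33 (adjusted p = 0.00195) and -0.51 (adjusted p = 0.000218).

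Of 37 region pairs, 4 were higher and 3 lower in trunk Del(CBS1) than in WT, 11 higher and 11 lower in Del(CBS1-3), and 9 higher and 14 lower in Del(CBS1-5). The Del(CBS1) pairs included C-DOM with the middle part holding Hoxd11 to Hoxd8 (-0.085, SE 0.016, adjusted p = 0.0183 in limma) and C-DOM with the 3-prime part holding Hoxd4 to Hoxd1 (0.12, SE 0.032, adjusted p = 0.0496). The first was lost without WT library 1 (adjusted p = 0.0688) or Del(CBS1) library 1 (0.0943). The second was lost without WT library 1 (0.134), WT library 2 (0.0819), Del(CBS1) library 1 (0.0943) or Del(CBS1) library 2 (0.163). The Del(CBS1) count of 7 fell to 3 without WT library 1, to 2 without Del(CBS1) library 1, and to 0 with coverage divided out or with library totals. It was 2 with only the 2 genotypes fitted and 3 with all 16 libraries. With library totals the counts were 9 in Del(CBS1-3) and 10 in Del(CBS1-5). The Del(CBS1-5) count of 23 fell to 14 without WT library 2.

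In trunk Del(CBS1), 9 of 6518 pairs of 40-kb bins were higher and 36 lower than in WT, and 645 had an unadjusted p below 0.05 in limma. A C-DOM bin at 74360001 to 74400000 rose with the Mtx2 bin at 74840001 to 74880000, from 108 ± 15.2 to 164 ± 2.60 contacts (n = 2 each, log2 0.61, SE 0.17, adjusted p = 0.0426). Further C-DOM bins rose with proximal T-DOM bins, at 74280001 with 74920001 (0.47), 74200001 with 75000001 (0.44) and 74000001 with 74920001 (0.43). Contacts of the first C-DOM bin after Atp5g3 (73920001) with the bin of Hnrnpa3 and Nfe2l2 (75640001) fell from 112 ± 1.32 to 65.2 ± 9.0 (-0.77, adjusted p = 0.0426). The Pde11a bin at 76120001, a phosphodiesterase gene, fell with the Ttn bin at 76960001 (-0.62, adjusted p = 0.0195), with 75120001 (-0.56) and with the Gm50595 bin at 75480001 (-0.52), and the bin of Cyct and Rbm45 (76360001) fell with 75720001 (-0.56). The rise of 1.64 between 72680001 and the same Cyct and Rbm45 bin rested on 10.1 pairs per library. Of the 36 lower bin pairs, 28 lay within the telomeric flank, around Pde11a, Cyct, Rbm45, Osbpl6 and Ttn. The bins in those pairs held 13.6 and 13.8% of all pair ends in the WT libraries and 12.9 and 12.7% in the Del(CBS1) libraries. With coverage divided out the count of 45 fell to 7. It was 20 without WT library 1, 0 without WT library 2, 15 without Del(CBS1) library 1 and 14 without Del(CBS1) library 2, so each pair named here was lost without WT library 2. It was 19 with 20-kb bins, 27 with the trend fit of limma and 26 with a separation of at least 100 kb.

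In trunk Del(CBS1-3), 31 bin pairs were higher and 19 lower than in WT, with 651 at an unadjusted p below 0.05. The bin of Hoxd11 to Hoxd8 and the start of Hoxd3 (74680001) lost contacts with the Gm50595 bin at 75560001, from 832 ± 4.53 to 569 ± 37.4 (n = 2 each, log2 -0.56, SE 0.079, adjusted p = 2.96e-08 in limma), in both libraries and in every setting run with these 40-kb bins on trunk. The Evx2 to Hoxd11 bin (74640001) lost contacts with 75760001 (-0.73, adjusted p = 0.00019) and the bin of Hoxd3 and Hoxd4 (74720001) with that of Agps and Ttc30b (75920001; -0.60, adjusted p = 0.0121). The Lnpk bin at 74520001 gained contacts with the T-DOM bin at 75040001, from 207 ± 25.3 to 306 ± 12.7 (0.56, adjusted p = 0.00488). The same C-DOM bin as in Del(CBS1) gained contacts with Mtx2 (0.66, adjusted p = 0.0278), and 74280001 with 74920001 (0.54, adjusted p = 0.00237). The Agps bin (75800001) rose with the Osbpl6 bin (76560001; 0.61), and the Pde11a bin fell with the Ttn bin (-0.62). A rise of 1.63 between 72560001 and the bin of Plekha3 and Ttn (76680001) and a fall of -1.54 between the Cdca7 bin (72440001) and Ttn (76760001) rested on 11.9 and 10.8 pairs per library. By region, 18 of 216 bin pairs between the C-DOM and the proximal T-DOM were higher, and 207 of the 216 had a positive change (median 0.25). The count of 50 fell to 12 without WT library 1, to 3 without WT library 2, to 10 without Del(CBS1-3) library 1, and to 21 with coverage divided out. It was 14 with library totals, 19 with 20-kb bins and 24 with only the 2 genotypes fitted. The Lnpk pair was lost without WT library 2 (0.44, adjusted p = 0.364) or Del(CBS1-3) library 1 (0.61, 0.0689). The Evx2 pair was lost without WT library 1 (-0.62, 0.0704) or Del(CBS1-3) library 1 (-0.66, 0.143).

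In trunk Del(CBS1-5), 109 bin pairs were higher and 65 lower than in WT, with 755 at an unadjusted p below 0.05. The bin of Hoxd11 to Hoxd8 (74680001) fell with the Gm50595 bins at 75560001, from 832 ± 4.53 to 451 ± 12.1 contacts (n = 2 each, log2 -0.89, SE 0.081, adjusted p = 3.07e-21 in limma), and at 75520001, from 530 ± 19.6 to 294 ± 4.0 (-0.85, adjusted p = 9.56e-14). It also fell with the bin of Ttc30a1, Ttc30a2 and Pde11a at 75960001 (-0.92, adjusted p = 8.58e-08). These 3 falls were seen in both libraries and passed in every setting run with these 40-kb bins on trunk. C-DOM bins rose with the Mtx2 bin (74360001, 0.81, adjusted p = 0.000262) and with 75000001 (from 74200001, 0.68, adjusted p = 1.22e-05). The rise with Mtx2 was lost without WT library 1 (0.66, adjusted p = 0.119) or Del(CBS1-5) library 2 (0.58, 0.175), and that with 75000001 without WT library 1 (0.52, 0.0646). Of the 109 higher pairs, 85 joined the C-DOM to the proximal T-DOM, where 213 of 216 pairs had a positive change (median 0.33). All 11 pairs of the middle part with the distal T-DOM were lower (median -0.58). Pairs with fewer reads were the Lnpk bin at 74480001 with 72520001 (0.80), the Sp3 bin at 72960001 with 75320001 (1.19), the bin of Cyct and Rbm45 with 72680001 (1.40) and with 72400001 (-1.63), and 74200001 with the Ttn bin at 76760001 (-1.16). The count of 174 was 60 without WT library 1, 57 without WT library 2 and 59 without Del(CBS1-5) library 2, 102 with library totals and 78 with 20-kb bins. Among all tested bin pairs the groups did not overlap in 39.7, 38.2 and 39.9% for the 3 mutants, where 33.3% would do so by chance.

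Several of the named pairs and bins depended on single libraries, given here with the adjusted p from limma without each. In Del(CBS1-3) the rise with Mtx2 was lost without WT library 1 (0.429), WT library 2 (0.137), Del(CBS1-3) library 1 (0.197) or Del(CBS1-3) library 2 (0.0771), and the rise of 74280001 with 74920001 without WT library 1 (0.225), WT library 2 (0.0638) or Del(CBS1-3) library 1 (0.347). The fall of Hoxd3 and Hoxd4 with Agps and Ttc30b was lost without WT library 1 (0.125), WT library 2 (0.180) or Del(CBS1-3) library 2 (0.375), and the rise of Agps with Osbpl6 without WT library 1 (0.227), WT library 2 (0.200) or Del(CBS1-3) library 1 (0.505). The fall of Pde11a with Ttn was lost without WT library 1 (0.0679), WT library 2 (0.467), Del(CBS1) library 2 (0.0513), Del(CBS1-3) library 1 (0.159) or Del(CBS1-3) library 2 (0.245). The rise with Plekha3 and Ttn was lost without WT library 1 (0.414), WT library 2 (0.0764), Del(CBS1-3) library 1 (0.143) or Del(CBS1-3) library 2 (0.0792), and the fall of Cdca7 with Ttn without any of these 4 (0.399, 0.125, 0.423 and 0.137) or either Del(CBS1-5) library (0.0543 and 0.0554). In Del(CBS1-5) the Lnpk rise was lost without WT library 1 (0.0755), WT library 2 (0.696), Del(CBS1) library 1 (0.0597), Del(CBS1) library 2 (0.0607) or Del(CBS1-5) library 2 (0.475), and the Sp3 rise without WT library 1 (0.752), Del(CBS1-5) library 1 (0.145) or Del(CBS1-5) library 2 (0.0946). The pair of Cyct and Rbm45 with 72680001 was lost without WT library 1 (0.0799) or WT library 2 (0.548), that with 72400001 without WT library 2 (0.581) or Del(CBS1-5) library 2 (0.368), and the Ttn fall without WT library 1 (0.374), WT library 2 (0.0509), Del(CBS1-5) library 1 (0.0856) or Del(CBS1-5) library 2 (0.389).

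Contacts of the 3 cluster parts were then followed along 919 bins of 10 kb. In Del(CBS1-5) the middle part, from Hoxd11 to Hoxd8, lost contacts with 25 of 45 bins of the distal T-DOM, and all 45 had negative values (median -0.67). The bin at 75570001 in Gm50595 fell from 199 ± 0.458 to 85.3 ± 6.60 contacts (n = 2 each, log2 -1.24, SE 0.16, adjusted p = 1.39e-07 in limma), in both libraries and in every setting run with these 10-kb bins on trunk. The middle part also fell at 75960001 (-1.32), and the 5-prime part with Evx2 fell in Agps (75830001, -1.50), at 75720001 (-1.28) and in Gpr155 (73340001, -1.53). The 3-prime part with Hoxd4 to Hoxd1 rose with C-DOM bins at 73970001 (0.74, adjusted p = 0.00663), 74480001 (0.75), 74130001 (0.60) and 74250001 (0.58), and the 5-prime part with Chrna1 (73570001, 0.66). In total 6 bins were higher and 62 lower, a count of 68 that was 37 without WT library 1, 37 without WT library 2, 31 without Del(CBS1-5) library 1 and 11 without Del(CBS1-5) library 2. In Del(CBS1-3) 3 bins passed: the middle part fell at 75580001 in Gm50595, from 178 ± 10.0 to 108 ± 3.80 (-0.71, adjusted p = 0.0127), the 5-prime part rose at 74770001 (0.68, adjusted p = 0.0141), and the 3-prime part rose at 72490001 (2.04, 11.3 pairs per library). That count was 0 without WT library 2, Del(CBS1) library 1 or Del(CBS1-3) library 2, 1 without Del(CBS1-3) library 1, and 18 with 20-kb bins. In Del(CBS1) limma called 0 bins, with 84 at an unadjusted p below 0.05, and 1 bin without WT library 1 or WT library 2. It called 2 bins with only the 2 genotypes fitted and 1 with 20-kb bins. The 919 changes had groups that did not overlap in 40.4, 42.4 and 52.1%, against 33.3% by chance.

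Among the profile bins of Del(CBS1-5), that of the middle part in Gm50595 passed whichever library was left out. The falls at 75960001 and in Agps were lost without Del(CBS1-5) library 2 (adjusted p 0.103 and 0.185 in limma), that at 75720001 without WT library 1 (0.134), Del(CBS1-5) library 1 (0.118) or Del(CBS1-5) library 2 (0.119), and that in Gpr155 without WT library 1 (0.153), Del(CBS1-5) library 1 (0.0611) or Del(CBS1-5) library 2 (0.203). The rise of the 3-prime part, with Hoxd4 to Hoxd1, at 73970001 was lost without WT library 1 (0.146) or Del(CBS1-5) library 2 (0.103). Its rise at 74480001 was lost without WT library 1 (0.432), WT library 2 (0.058), Del(CBS1-3) library 1 (0.0588), Del(CBS1-3) library 2 (0.0657), Del(CBS1-5) library 1 (0.0748) or Del(CBS1-5) library 2 (0.196). Its rise at 74250001 was lost without WT library 1 (0.198), WT library 2 (0.177), Del(CBS1-3) library 2 (0.0505), Del(CBS1-5) library 1 (0.105) or Del(CBS1-5) library 2 (0.185). Its rise at 74130001 and that of the 5-prime part in Chrna1 were lost without any of the 8 libraries, with an adjusted p of 0.0503 to 0.262 and 0.0561 to 0.463. In Del(CBS1-3) all 3 named bins were lost without Del(CBS1-3) library 1 (0.268 each), and the 5-prime rise at 74770001 also without WT library 1 (0.0632).

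**Figure D2:**
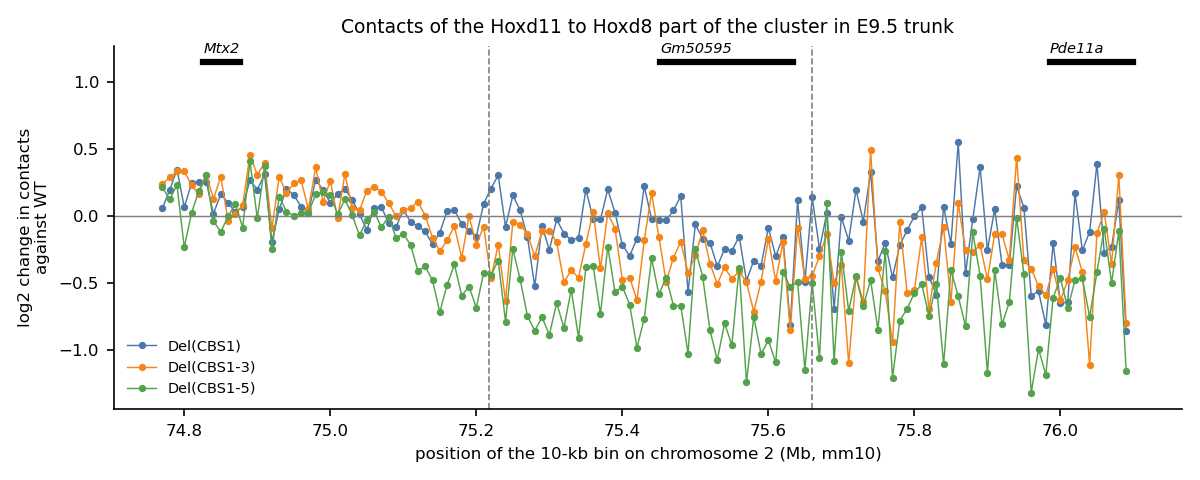
Log2 change against WT in contacts of the part of the cluster from Hoxd11 to Hoxd8 with 10-kb bins on its telomeric side in E9.5 trunk (2 libraries per genotype). Dashed lines mark the middle and the end of the T-DOM, and black bars mark Mtx2, Gm50595 and Pde11a.

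The balance of each gene between the domains was read as the log2 ratio of T-DOM to C-DOM contacts of its start site. The Lnpk window (74576958 to 74581957) lay inside the C-DOM and the Mtx2 window (74823312 to 74828311) inside the proximal T-DOM. In trunk and limb their ratios set contacts within their own domain against contacts across the cluster. They are therefore not separate from the C-DOM to T-DOM contacts above. The Hoxd10 window (74681773 to 74686772) lay inside the record of Hoxd11 (74679558 to 74687016). Values given for Hoxd10, in trunk and limb, therefore describe that stretch and not a gene apart from Hoxd11. In WT trunk the ratio rose from gene to gene up to Hoxd3, was close to that at Hoxd4, and rose again to Mtx2. It went from -1.51 ± 0.082 at Lnpk (mean ± SD, n = 2), -0.53 ± 0.071 at Evx2 and -0.33 ± 0.058 at Hoxd13, through -0.021 ± 0.036 at Hoxd12, 0.20 ± 0.0071 at Hoxd11, 0.45 ± 0.049 at Hoxd10 and 1.06 ± 0.091 at Hoxd9, to 1.41 ± 0.13 at Hoxd8, 1.75 ± 0.16 at Hoxd3, 1.74 ± 0.086 at Hoxd4, 2.01 ± 0.036 at Hoxd1 and 2.2 ± 0.00053 at Mtx2. In Del(CBS1) the ratio of Lnpk was 0.22 higher (SE 0.076, adjusted p = 0.0380 in limma), that of Hoxd4 0.25 lower (adjusted p = 0.0380) and that of Hoxd3 0.31 lower (adjusted p = 0.0216), in both libraries. None of these held throughout. The count of 3 was 0 without WT library 1, Del(CBS1) library 1 or Del(CBS1) library 2, and 1 without WT library 2, Del(CBS1-5) library 1 or Del(CBS1-5) library 2. It was 1 with windows of 10 kb, with windows at gene ends and with all 16 libraries. Contacts of each gene with single domains (48 values) gave 0 calls by limma in Del(CBS1), with 13 at an unadjusted p below 0.05. Del(CBS1-3) and Del(CBS1-5) gave 25 calls each.

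In Del(CBS1-3) the ratio was higher at genes on the centromeric side and lower at genes on the telomeric side. Lnpk and Mtx2, the outermost of these, lie inside the domains. The ratio rose at Lnpk (0.24, SE 0.076, adjusted p = 0.00797 in limma), Evx2 (0.27, adjusted p = 0.00512), Hoxd13 (0.22, 0.0125), Hoxd12 (0.25, 0.00738) and Hoxd10 (0.31, 0.00337). It fell at Hoxd8 (-0.30, adjusted p = 0.00512), Hoxd4 (-0.25, 0.0125), Hoxd3 (-0.47, 0.00024), Hoxd1 (-0.33, 0.00192) and Mtx2 (-0.19, 0.0332). Values of 0.13 at Hoxd11 and 0.049 at Hoxd9 did not pass. With the proximal T-DOM alone, Evx2 and Hoxd12 rose by 0.28 each (adjusted p = 0.00502), and with the distal T-DOM Hoxd9 fell by -0.52 (adjusted p = 0.000373) and Hoxd8 by -0.50 (adjusted p = 0.00197). Without WT library 2 the count of 10 was 6, and Hoxd13 (0.18, adjusted p = 0.0768), Hoxd8 (-0.21, 0.120), Hoxd4 (0.0736) and Mtx2 (0.103) were lost. Fitting only the 2 genotypes also gave 6, with the same genes lost (adjusted p 0.0509, 0.0602, 0.0987 and 0.0571 in the same order). Hoxd4 was lost without WT library 1 (0.188) or Del(CBS1-3) library 1 (-0.10, 0.210), and Mtx2 without WT library 1 (0.104) or either Del(CBS1-5) library (0.0774 each). Hoxd9 was 0.24 (adjusted p = 0.00671) without Del(CBS1-3) library 1, and -0.14 without Del(CBS1-3) library 2. With windows at gene ends the count was 6, Hoxd10 was 0.074 (adjusted p = 0.352), Evx2, Hoxd13, Hoxd12 and Hoxd8 were lost, and Hoxd11 passed (0.38, adjusted p = 0.0124). Hoxd11 also passed with 10-kb windows (0.22, adjusted p = 0.00233). The window at the end of Hoxd10 (74695106) overlapped the start window of Hoxd9 (74695263 to 74700262). That at the end of Hoxd11 (74687016) overlapped the start window of Hoxd10 (74681773 to 74686772). The end windows of Hoxd10 and Hoxd11 thus partly repeat a neighbouring gene and do not measure the same stretch again.

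In Del(CBS1-5) the ratio fell from Hoxd9 to Mtx2 and rose at Lnpk. Lnpk rose by 0.33 (SE 0.076, adjusted p = 0.000769 in limma), and Hoxd8 (-0.49), Hoxd4 (-0.50) and Hoxd3 (-0.53) fell with an adjusted p of 4.10e-05 each, in both libraries. Hoxd9 (-0.33, adjusted p = 0.0046), Hoxd1 (-0.26, 0.00546) and Mtx2 (-0.20, 0.0286) were lower. Evx2 (0.080), Hoxd13 (0.097), Hoxd12 (0.037), Hoxd11 (-0.077) and Hoxd10 (-0.15) did not pass. With the distal T-DOM alone, Hoxd8 (-0.74), Hoxd9 (-0.71), Hoxd10 (-0.60), Hoxd11 (-0.57), Hoxd4 (-0.50), Hoxd3 (-0.44), Hoxd12 (-0.44) and Evx2 (-0.31) fell, and Lnpk rose (0.28, adjusted p = 0.0399). With the C-DOM, Hoxd3 (0.27), Hoxd4, Hoxd1 and Mtx2 (0.24 each) rose. Leaving out WT library 1 gave a count of 4 in place of 7, with Hoxd9 (adjusted p = 0.065), Hoxd1 (0.065) and Mtx2 (0.0998) lost. Hoxd9 was lost without WT library 2 (0.163), Hoxd1 without Del(CBS1-5) library 2 (0.133), and Mtx2 without WT library 2 (0.115), Del(CBS1-5) library 1 (0.0868) or Del(CBS1-5) library 2 (0.293). Hoxd10 passed without Del(CBS1-3) library 1 or 2 (0.0412 each) and with windows at gene ends (-0.31, 0.00643), where Hoxd8 did not (-0.30, 0.0588). The window at the end of Hoxd10 overlapped the start window of Hoxd9, which was lower as well. Among the other 27 genes of the captured region limma called 0 in each mutant, with 1, 2 and 2 at an unadjusted p below 0.05. Their SE of 0.16 to 0.20, against 0.076 to 0.095 at the 12 genes above, left changes of the size called there harder to detect. The largest changes were at Sp3, chosen after its values were seen, with 0.59, 0.46 and 0.66 (adjusted p 0.154, 0.567 and 0.0649).

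**Figure D3:**
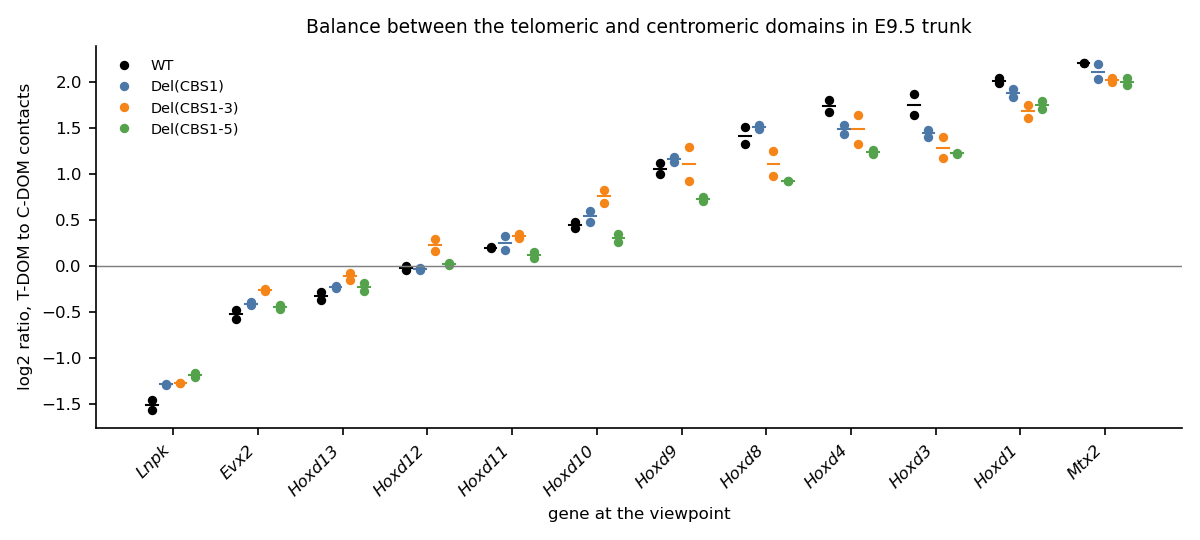
Log2 ratio of T-DOM to C-DOM contacts of the start sites of 12 genes in E9.5 trunk. Points are the 2 libraries of WT, Del(CBS1), Del(CBS1-3) and Del(CBS1-5), and short lines are their means.

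Direct tests between mutants found differences in contacts of the middle and 5-prime parts, from Evx2 to Hoxd8, and in the ratios of several genes. Del(CBS1-5) had fewer contacts than Del(CBS1-3) between the middle part and both the distal T-DOM (-0.38, SE 0.032, adjusted p = 0.00077 in limma) and the proximal T-DOM (-0.22, adjusted p = 0.00958), in every setting tried on region pairs. It had fewer contacts of the 5-prime part with the distal (-0.30, adjusted p = 0.00077) and proximal T-DOM (-0.18, adjusted p = 0.00387), the latter lost with coverage divided out (-0.085, 0.0854). Hoxd10 (-0.45, adjusted p = 0.000107), Hoxd9 (-0.38), Hoxd4 (-0.25), Hoxd12 (-0.21), Hoxd11 (-0.21) and Evx2 (-0.19) had lower T-DOM to C-DOM ratios in Del(CBS1-5) than in Del(CBS1-3). Against Del(CBS1), in the same run, Del(CBS1-5) lost contacts of the middle part with the distal T-DOM (-0.56, SE 0.032, adjusted p = 0.000117) in every setting tried on region pairs. C-DOM contacts with the T-DOM rose by 0.14 (adjusted p = 0.000198), a rise lost with library totals (0.060, 0.391). The ratio fell at Hoxd8 (-0.58, adjusted p = 9.47e-06), Hoxd9 (-0.43), Hoxd4 (-0.25), Hoxd10 (-0.24) and Hoxd3 (-0.22). Del(CBS1-3) exceeded Del(CBS1) in C-DOM to T-DOM contacts by 0.093 (adjusted p = 0.00304), which was lost with library totals (0.036, 0.581), and its ratio was higher at Hoxd12 (0.26) and lower at Hoxd8 (-0.40).

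Differences between mutants in the number of region pairs moved with single libraries. C-DOM to T-DOM contacts were 0.046 higher in Del(CBS1-5) than in Del(CBS1-3) (SE 0.011, adjusted p = 0.0269 in limma). This was lost without WT library 1 or 2 (0.0523 each), Del(CBS1) library 1 or 2 (0.0585 each), Del(CBS1-3) library 1 (0.0855), Del(CBS1-3) library 2 (0.121), Del(CBS1-5) library 1 (0.0567) or Del(CBS1-5) library 2 (0.0834). Del(CBS1-3) and Del(CBS1) differed in 15 region pairs, or 7 without Del(CBS1) library 1, 9 without Del(CBS1) library 2, 8 without Del(CBS1-3) library 1, 6 without Del(CBS1-3) library 2 and 8 with library totals. Del(CBS1-5) and Del(CBS1-3) differed in 11, or 6 without Del(CBS1-3) library 1, 4 without Del(CBS1-3) library 2, 7 without Del(CBS1-5) library 1, 4 with library totals and 6 with all 16 libraries. Del(CBS1-5) and Del(CBS1) differed in 25, or 14 without Del(CBS1) library 2 and 10 with library totals. Bin pairs called were 4, 31 and 126 for these comparisons in the same order, and cluster profile bins 0 (66 at an unadjusted p below 0.05 in limma), 10 and 30.

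Insulation of the border between C-DOM and Evx2, at 74640000, was not called different in any mutant. The score, which is lower at stronger borders, changed by 0.057 in Del(CBS1) (SE 0.031, adjusted p = 0.277 in limma), 0.036 in Del(CBS1-3) (adjusted p = 0.625) and 0.045 in Del(CBS1-5) (adjusted p = 0.351). Inside the cluster the score rose. At 74700000, in the end of Hoxd9, the differences were 0.10 (SE 0.025, adjusted p = 0.0291), 0.22 (adjusted p = 0.00314) and 0.20 (adjusted p = 0.0074) in limma. Of 11 positions from Evx2 to Hoxd1, 7, 10 and 10 were higher and 0 lower. Their 200-kb diamonds overlap, so these positions are not independent of each other. Over all 420 positions, 16, 20 and 49 were higher and 49, 23 and 43 lower. The largest differences lay at 74730000 near Hoxd4 in Del(CBS1) (0.16) and at 74720000 in Del(CBS1-3) (0.24) and Del(CBS1-5) (0.21). The own lowest position was 74640000 (-0.72) and 74630000 (-0.73) in the WT libraries, and 74630000 in each mutant library. At the Evx2 border a 400-kb window gave rises of 0.10 (adjusted p = 0.0381), 0.13 (0.0295) and 0.18 (0.00531), a 100-kb window turned the Del(CBS1-5) value to -0.012, coverage divided out gave 0.10 in Del(CBS1-5) (0.0156), and a fit of only the 2 genotypes called the Del(CBS1) value (0.0124). The Del(CBS1-3) value was -0.0071 without Del(CBS1-3) library 1. The rise at 74700000 in Del(CBS1) was lost without WT library 1 (0.12), WT library 2 (0.088), Del(CBS1) library 1 (0.12) or Del(CBS1) library 2 (0.085). In Del(CBS1-5) it was lost without WT library 2 (0.18, 0.0696) or Del(CBS1-5) library 2 (0.17, 0.0856).

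**Figure D4:**
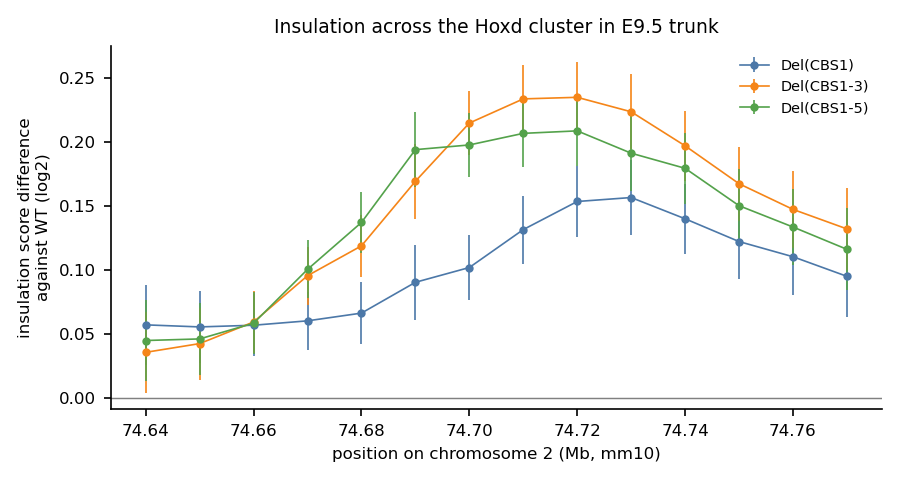
Difference of the insulation score against WT at 10-kb positions across the Hoxd cluster in E9.5 trunk (2 libraries per genotype, bars SE). Higher values mean more contacts across a position.

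Among 43 pairs of Hoxd and Evx2 start sites inside the cluster, limma called 0 changed in each mutant, with 0, 2 and 2 at an unadjusted p below 0.05. Without WT library 1 the count was 1 in each mutant, and with 10-kb windows it was 2 in Del(CBS1-3). The median pair of genes had 29.8 read pairs per library (range 11.5 to 81.5), and the size of change that these depths could reveal was not simulated.

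In limb, contacts between the C-DOM and the T-DOM were higher in Del(CBS1-3) and Del(CBS1-5) than in WT, with 1 library per genotype. In DFL the log2 ratios were 0.22 (0.21 to 0.23) and 0.34 (0.33 to 0.35), and in PFL 0.14 (0.13 to 0.15) and 0.23 (0.21 to 0.24). Del(CBS1) gave -0.043 in DFL (-0.057 to -0.029) and -0.068 in PFL (-0.081 to -0.055). With library totals the DFL values were -0.022, 0.27 and 0.44, and the PFL values of Del(CBS1-3) and Del(CBS1-5) 0.16 and 0.26. Within the run shared by the limb mutants, Del(CBS1-3) exceeded Del(CBS1) by 0.26 in DFL and 0.21 in PFL, and Del(CBS1-5) exceeded it by 0.39 and 0.29. The middle part with Hoxd11 to Hoxd8 had fewer contacts with the distal T-DOM in Del(CBS1-5) than in Del(CBS1), by -0.39 in DFL (-0.44 to -0.33) and -0.37 in PFL (-0.42 to -0.32). Against WT these ratios were -0.40 in DFL and -0.15 in PFL, and in PFL Del(CBS1) was 0.22 (0.17 to 0.27) above WT. Contacts of the 5-prime part with Evx2 to Hoxd12 and the distal T-DOM were higher in Del(CBS1-5) than in Del(CBS1), by 0.18 in DFL and 0.13 in PFL, where trunk had -0.34.

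At single genes in limb, Hoxd4, Hoxd3 and Hoxd8 had the lowest T-DOM to C-DOM ratios relative to WT in Del(CBS1-3) and Del(CBS1-5). In DFL the changes were -0.66 (-0.80 to -0.52) at Hoxd4, -0.57 at Hoxd3 and -0.42 at Hoxd8 in Del(CBS1-3), and -0.87 (-1.02 to -0.73), -0.95 and -0.77 in Del(CBS1-5). In PFL they were -0.69 (-0.83 to -0.55), -0.40 and -0.33 in Del(CBS1-3), and -0.78 (-0.92 to -0.64), -0.50 and -0.41 in Del(CBS1-5). The largest rises in DFL were at Hoxd10 (0.25), Lnpk (0.21) and Hoxd13 (0.17) in Del(CBS1-3), and at Lnpk (0.55), Evx2 (0.37) and Hoxd13 (0.31) in Del(CBS1-5). In PFL they were at Hoxd11 (0.37), Hoxd10 (0.36) and Hoxd12 (0.35) in Del(CBS1-3), and at Hoxd12 (0.43), Hoxd11 (0.32) and Hoxd13 (0.31) in Del(CBS1-5). Del(CBS1) was lower at Hoxd4 in both tissues (-0.29 and -0.31), at Hoxd10 (-0.24) and Evx2 (-0.18) in DFL, and at Lnpk (-0.20) and Hoxd13 (-0.14) in PFL. It was higher in PFL at Hoxd8 (0.30), Hoxd9 (0.18) and Hoxd10 (0.16), and in DFL the highest values, 0.12 at Mtx2 and 0.042 at Lnpk, had intervals that included 0. Mutants and WT came from different runs and studies, so genotype and study cannot be separated in the values against WT. Against Del(CBS1) of the same run, Del(CBS1-5) was lower at Hoxd8 (-0.76 in DFL and -0.70 in PFL), Hoxd3 (-0.79 and -0.55) and Hoxd4 (-0.58 and -0.47). Del(CBS1-3) was lower too, at Hoxd8 (-0.40 and -0.63), Hoxd3 (-0.41 and -0.46) and Hoxd4 (-0.37 and -0.38). All 12 intervals lay below 0.

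In limb the Evx2 border at 74640000 had higher insulation scores than WT in each mutant. The differences were 0.11 (0.072 to 0.15), 0.18 (0.15 to 0.21) and 0.22 (0.19 to 0.26) in DFL, and 0.053 (0.014 to 0.091), 0.16 (0.13 to 0.20) and 0.10 (0.065 to 0.14) in PFL. With a 100-kb window they were 0.15, 0.14 and 0.18 in DFL, and 0.10 for Del(CBS1) and 0.044 for Del(CBS1-5) in PFL. The WT libraries came from another run and study, so genotype and study cannot be separated in these differences. In the run of the mutants, the scores of Del(CBS1), Del(CBS1-3) and Del(CBS1-5) were -0.91, -0.85 and -0.80 in DFL, and -1.04, -0.93 and -0.99 in PFL. The lowest score in DFL lay at 74700000 in Hoxd9 in WT (-1.14), 74690000 in Del(CBS1) (-1.17), 74680000 by Hoxd11 in Del(CBS1-3) (-1.09) and 74650000 before Evx2 in Del(CBS1-5) (-0.84). In PFL it lay at 74640000 in all 4 libraries.

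With all 16 libraries fitted together and tissue as a covariate, 3 region pairs and 1 viewpoint changed in Del(CBS1). C-DOM contacts with the middle part holding Hoxd11 to Hoxd8 were 0.10 higher in Del(CBS1-5), and contacts of the middle part with the proximal T-DOM turned from -0.11 (adjusted p = 0.0498 in limma) to 0.038. A search for deleted restriction fragments between Lnpk and Mtx2 found 0 footprints in each mutant, with 6 to 8 of 760 fragments lacking read ends. Read ends are placed at fragment midpoints, so a deletion inside a fragment could not show. The positions of the deletions were not available, so this search neither identifies nor rules out the genotypes. In an inspection made after the values were seen, the fragment at 74694315, within Hoxd10, had 1.42 log2 more of the cluster's read ends in trunk Del(CBS1-3) and Del(CBS1-5) than in the other trunk libraries. The next largest such difference among 185 fragments was 0.29.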

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

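The tests of the sequencing run, of coverage and of the shared chromosome feature, and the use of the difference between trunk replicates as a spread, were chosen after the results were seen, and those of the limb tissues of the same run, of the distance decay and of the Del(CBS1) genotype were written before. The fall in contacts between the middle part of the cluster, with Hoxd11 to Hoxd8, and the distal T-DOM in trunk Del(CBS1-5) was weighed against a run effect, against coverage and against the genotype. Against Del(CBS1) in the same run the change was -0.56 (SE 0.032), which a run effect alone would not give. Against WT it was -0.68, and -0.56 (SE 0.030) with the coverage of both regions divided out, so coverage did not account for the whole fall. Coverage was counted on the same pairs and falls with contacts, so whether it caused the rest cannot be told. Against Del(CBS1) of the same limb run the change was -0.37 in PFL, the weaker tissue, with an interval up to -0.32. In PFL Del(CBS1) lay above WT, unlike in trunk, so the fall of Del(CBS1-5) against WT was smaller there. A loss of CTCF sites that hold this part of the cluster against the distal T-DOM stays a candidate explanation, offered as a hypothesis. CTCF binding and the positions of the sites were not analysed here.

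Bin pairs within the telomeric flank, around Pde11a, Cyct, Rbm45, Osbpl6 and Ttn, were lower in trunk Del(CBS1) (median log2 change -0.32 over 28 pairs). These pairs were picked as called lower than the WT libraries, so medians against WT are partly set by that choice. Over the whole flank, normalized contacts were 351720 ± 4024 in WT, 338845 ± 726 in Del(CBS1), 342667 ± 1792 in Del(CBS1-3) and 357808 ± 6995 in Del(CBS1-5) (n = 2 each). Del(CBS1-5) of the same run had a median of -0.085 over the picked pairs. The choice of pairs favours a larger fall in Del(CBS1), so that comparison does not decide on a run effect. Over the whole flank, not limited to the picked pairs, the mean of Del(CBS1-5) lay above WT and that of Del(CBS1) below. A fall shared by the run was not seen there. The distance decay as the whole cause was argued against by Del(CBS1-3), where the replicate with fewer short pairs differed by 0.0035, above the bound set beforehand by more than the largest difference between trunk replicates (0.13), while the -0.13 in Del(CBS1-5) leaves a part open. The Del(CBS1) genotype stays open. Del(CBS1-3) also had a median of -0.21 in trunk, but against the same WT libraries that were used to pick the pairs. Chance-high WT values in these pairs would lower both medians. In limb Del(CBS1) differed from Del(CBS1-3) by only -0.023 in DFL and 0.020 in PFL, which goes against an effect particular to Del(CBS1). Those limb values come from single libraries and lie within the largest difference between trunk replicates. Lower coverage of these bins is another candidate explanation. With coverage divided out the median was -0.014, with 15 of 28 pairs still negative. Coverage was counted on the same pairs, so a fall in contacts would lower it too. The correction therefore cannot tell lower coverage from a fall in contacts. A further candidate is a feature of the chromosome shared by Del(CBS1) and Del(CBS1-3), both lower than WT and Del(CBS1-5) in each limb tissue. The smallest of these differences (-0.1298, Del(CBS1-3) against WT in DFL) barely exceeds in size the largest difference between trunk replicates (0.1289). All come from single limb libraries, with WT from another study, so they do not decide. A sequence variant carried with the allele was not tested.

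The tests on the fragment at 74694315, within Hoxd10, were all chosen after its values were seen. Its higher share of read ends in Del(CBS1-3) and Del(CBS1-5) was not explained by the run, since the difference within a run was at least 0.86, against 1.11 over all libraries. The alleles are a candidate explanation, as the limb libraries of these genotypes lay above the 4 others with a gap of 0.53 at a fragment picked in trunk only, although 12 of 185 fragments separated these limb libraries fully in one direction or the other. Whether a deletion changed the fragment itself could not be read from the files.

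In Del(CBS1), C-DOM to T-DOM contacts differed in sign between trunk (0.093) and limb, with differences of -0.14 for DFL and -0.16 for PFL that were not tested. The T-DOM to C-DOM ratio in Del(CBS1) differed between trunk and DFL at Evx2 by -0.29, between DFL and PFL at Hoxd10 by 0.40, and between trunk and PFL at Hoxd13 by -0.23 and at Lnpk by -0.43, none of them tested. In Del(CBS1-5) it differed between trunk and PFL at Hoxd10 by 0.31 and at Hoxd11 by 0.39, and between trunk and DFL at Hoxd11 by 0.22, again not tested. Tissue, stage, run and, for WT, study all changed together between these libraries.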

How the results depend on the processing

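The settings named here were planned except the windows at gene ends, added after the data were examined, and the listing of single region pairs and genes was restricted after the list of reversals was seen. In none of these cases was the cause tested unless the paragraph says so.

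Dividing out coverage gave 7 changed bin pairs in Del(CBS1) and 21 in Del(CBS1-3), 0 region pairs in Del(CBS1), 0.048 for C-DOM x T-DOM and -0.0071 for C-DOM x distal T-DOM contacts in Del(CBS1), and in Del(CBS1-5) 0.094 for C-DOM x middle cluster part (adjusted p = 0.0114) and 0.10 for insulation at the HoxD border. The cause was not tested.

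With library totals the bin pairs were 14 in Del(CBS1-3) and 102 in Del(CBS1-5). The region pairs were 0 in Del(CBS1), 9 in Del(CBS1-3), 10 in Del(CBS1-5), 8 for Del(CBS1-3) against Del(CBS1), 4 for Del(CBS1-5) against Del(CBS1-3) and 10 for Del(CBS1-5) against Del(CBS1). In Del(CBS1), C-DOM x T-DOM contacts were 0.18, and the 5-prime cluster part with the distal T-DOM (0.035) and the telomeric flank (0.0082) and the 3-prime cluster part with the same regions (0.035 and 0.0017) turned positive. In limb, C-DOM x T-DOM contacts were -0.022, 0.27 and 0.44 in DFL, and 0.16 and 0.26 in PFL Del(CBS1-3) and Del(CBS1-5). The cause was not tested.

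Smaller bins of 20 kb gave 19, 19 and 78 changed bin pairs for the 3 mutants, and 20-kb profile bins 1 in Del(CBS1) and 18 in Del(CBS1-3). The trend fit of limma gave 27 bin pairs in Del(CBS1), and a separation of at least 100 kb 26. Fitting only the 2 genotypes gave 24 bin pairs in Del(CBS1-3), 2 profile bins and 2 region pairs in Del(CBS1), 6 viewpoints in Del(CBS1-3), and a called border insulation of 0.057 in Del(CBS1) (adjusted p = 0.0124). A replicate block gave 5 profile bins in Del(CBS1-3). Correlations that would show pairing by replicate number ranged from -0.022 to 0.023 over bin pairs, -0.21 to 0.46 over region pairs and -0.28 to 0.36 over viewpoints. The cause was not tested.

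All 16 libraries with tissue as covariate gave 3 region pairs in Del(CBS1) and 6 for Del(CBS1-5) against Del(CBS1-3), and 1 viewpoint in Del(CBS1). In Del(CBS1), C-DOM x T-DOM was 0.019, C-DOM x middle cluster part 0.011, C-DOM x distal T-DOM -0.032, 5-prime cluster part x proximal T-DOM -0.0080, Evx2 -0.0094 and Hoxd13 -0.016. In Del(CBS1-3) the 5-prime cluster part x distal T-DOM was 0.0087. In Del(CBS1-5), C-DOM x middle cluster part was 0.10, middle cluster part x proximal T-DOM 0.038 and Hoxd11 0.078. Domain limits from insulation minima gave 0.0089 for 3-prime cluster part x distal T-DOM in Del(CBS1). The cause was not tested.

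Windows of 10 kb gave 1 viewpoint in Del(CBS1), 2 gene pairs in Del(CBS1-3), 0.020 at Hoxd12 in Del(CBS1), -0.039 at Hoxd9 in Del(CBS1-3) and -0.015 at Hoxd12 in Del(CBS1-5). Windows at gene ends gave 1 viewpoint in Del(CBS1) and 6 in Del(CBS1-3), 0.0034 at Hoxd12 in Del(CBS1), -0.10 at Hoxd9 in Del(CBS1-3), and -0.027 at Evx2 and -0.0014 at Hoxd12 in Del(CBS1-5). A 400-kb insulation window gave 0.10, 0.13 and 0.18 at the border in trunk, and a 100-kb window -0.012 in trunk Del(CBS1-5), 0.15, 0.14 and 0.18 in DFL, and 0.10 and 0.044 in PFL Del(CBS1) and Del(CBS1-5). The cause was not tested.

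Leaving out 1 library at a time, the bin pairs ranged from 0 to 57 in Del(CBS1), 3 to 49 in Del(CBS1-3) and 57 to 199 in Del(CBS1-5), the profile bins from 0 to 1, 0 to 4 and 11 to 64, and the region pairs from 2 to 9 in Del(CBS1) and 14 to 21 in Del(CBS1-5). Region pairs ranged from 6 to 13 for Del(CBS1-3) against Del(CBS1), 4 to 10 for Del(CBS1-5) against Del(CBS1-3) and 14 to 24 for Del(CBS1-5) against Del(CBS1). Viewpoints ranged from 0 to 3, 6 to 10 and 4 to 8, and gene pairs from 0 to 1 in each mutant. In Del(CBS1), 3-prime cluster part x distal T-DOM ranged from -0.060 to 0.0016, Hoxd12 from -0.040 to 0.011, Hoxd11 from -0.023 to 0.13 and Hoxd8 from -0.00087 to 0.19. In Del(CBS1-3), 3-prime cluster part x proximal T-DOM ranged from -0.12 to 0.045, Hoxd9 from -0.14 to 0.24 and the border insulation from -0.0071 to 0.079. In Del(CBS1-5), C-DOM x middle cluster part ranged from -0.027 to 0.0032. The cause was not tested, and with 2 libraries per genotype each omission leaves 1 on that side.

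Of the alternatives to results that answer a comparison, 541 were labelled the same and 82 moved. A further 3 weakened and 5 strengthened a call, and 2 turned a direction. A count was labelled moved when it changed by more than 1.5 times, and a limb value when it left its counting interval. The 541 therefore include counts that changed by less, and the footprint settings, in which the same gaps were examined. Of the alternatives on single features, 1762 were the same, 357 weaker, 25 stronger and 31 reversed. Data were simulated once for single 40-kb bin pairs of Del(CBS1-5) against WT, with 2 libraries per genotype and a common dispersion of 0.005. There, 15 of 50 rises and 10 of 50 falls of log2 0.5 were called, and 42 and 34 of 50 at log2 1.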
